A study of Homo sapiens with 12 samples.

How the data were processed

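Poly(A)-selected RNA of CD8+ T cells from 12 samples was analysed, 4 each of Naive, Control and Tra2bPE, with the group and the replicate number taken from the labels. Per the labels' protocols, the cells came from blood mononuclear cells of healthy donors, RNA was extracted 48 h after the start of treatment, and libraries were made with a kit for very small RNA amounts that copies polyadenylated RNA. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.7.1a, handled with SAMtools 1.9, and quantified with StringTie 2.1.0, and R 4.0.5 with DESeq2 1.30.1 was used downstream. The deposited tables hold estimated counts per gene (61587 genes) and per transcript (244998 transcripts) for all 12 samples, made with StringTie per the submitters' processing notes. The values were already whole numbers, so rounding changed none of them, and the totals per library were the same in both tables.

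The total per library had a median of 389 M and a range of 288 to 518 M. In Naive it was 376 ± 108 M, in Control 431 ± 50.6 M and in Tra2bPE 346 ± 28.0 M (mean ± SD, n = 4). StringTie counts are derived from coverage, so these totals are on an estimated scale and the counting error of a low value cannot be read from them directly. No pair of replicates was a duplicate of another: the chi-square per degree of freedom of the 18 pairs within groups lay between 283 and 1397.

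Gene names, gene types and transcript models came from GENCODE release 29 on GRCh38. Of the gene IDs, 61415 matched, 56987 with the version and 4428 without it. Y-linked genes (556) and genes of X inactivation (3) were left out, 559 in all, which left 61028 genes. Of the transcripts, 83.1% were in the reference (203495). Transcript sums were equal to the gene count in every library for 92.2% of the 57837 genes with reference transcripts (53336 genes), and the 170851 transcripts of such genes, with 83.3% of all counts, were used for transcript shares.

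Gene tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling, the filterByExpr filter and the quasi-likelihood test, with all 12 samples in one fit and the Benjamini-Hochberg adjustment within each comparison (adjusted p below 0.05, two-sided). The gene tests kept the default prior count of edgeR, and a prior count of 1 was used for the log2 CPM values of the list tests. The comparisons were Control against Naive, Tra2bPE against Control and Tra2bPE against Naive. CPM values, the counts scaled to a common library size, were computed from the TMM-scaled totals. A group with no counts was given a floor of 3 counts per library, and its fold is stated as at least the value that this floor gives. The TRA2B transcripts with the poison exon were those whose annotated exons hold the whole exon, and their share of the gene's counts was compared by exact two-sided permutation of 4 against 4 samples (70 arrangements, smallest p 0.0286).

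Gene lists were written before the data were examined and tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The 32 lists were T cell identity, T cell activation, Cytotoxic effector, Naive and memory, Inhibitory receptors and exhaustion, Cytokines and chemokines, DNA replication, Mitosis, p53 targets, SR proteins and TRA2, SR protein kinases, hnRNP proteins, Core spliceosome, Nonsense-mediated decay, Glycolysis, Oxidative phosphorylation, Ribosome biogenesis, Cytosolic ribosomal proteins, Type I interferon response, Cholesterol synthesis, Integrated stress response, Unfolded protein response, Apoptosis regulators, Immediate early and heat shock, Mitochondrially encoded, Monocyte and macrophage markers, B cell markers, NK cell markers, CD4 T cell markers, Gamma delta and invariant T cell markers, Dendritic cell markers, and Platelet and red cell markers. A gene counted as risen or fallen by its adjusted p over all genes, and a further count used p-values adjusted over the list alone.

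The genes, lists, comparisons, tests and naming rule were fixed before the data were examined. The rule took, per gene comparison, the 10 largest rises and the 10 largest falls among named genes with adjusted p below 0.05, a mean of at least 5 CPM in a group and no overlap between the groups. Per list it took up to 4 members, first those past the threshold with the largest change and then, if fewer than 2 passed, the most abundant. TRA2B, TRA2A, IL2RA, GZMB, IFNG, MKI67, TCF7, CDKN1A and a further gene that is not reported here were always named, and for transcript usage TRA2B and the 10 genes with the smallest adjusted p. The text names part of the genes that the rule allows.

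Transcript usage was tested with diffSpliceDGE and Simes p-values per gene, as planned. After other divisions of the libraries gave many calls with it, a limma test on the arcsine of transcript shares was added, after 3 filters had been tried, with the filter of 1 CPM in 4 samples kept for the text. The relation of stimulation and ASO changes was set against 20 simulated data sets with no change and against fits with the Control libraries divided.

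Each test was run on data simulated for all 12 libraries from the Control means and the library sizes and dispersions of the data. In the Tra2bPE libraries 100 genes were changed per fold size. For the ASO comparison (25749 genes) edgeR recovered 9% of 2-fold and 67% of 4-fold changes with 3 false calls, DESeq2 41% and 89% with 81, limma-voom 8% and 66% with 1, and edgeR with the replicate number as a block 4% and 64% with 0. Camera found the 1 changed list and called none of the others. The genes were simulated independently of each other, so this cannot show how the list test behaves when the genes of a list are correlated. For transcript usage in the ASO comparison (9976 genes) the planned test recovered 2% and 1% with 105 false calls, the gene-level F test 1% and 7% with 53, and limma-voom diffSplice 1% and 24% with 65, and the added test of shares (6571 genes) recovered 0% of either size with 0 false calls. At a dispersion of 0.05, lower than that of the data, the planned test (10228 genes) recovered 34% and 100% with 53 false calls and the added test (6539 genes) 12% and 82% with 6.

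The alternatives planned were DESeq2 1.42.0 size factors, upper-quartile scaling, no filter, a filter of 1 CPM in 4 samples, the DESeq2 Wald test, limma-voom, a fit of the compared groups alone, the replicate number as a block, a minimum fold change of 2, an estimated correlation and fry for lists, other tests and filters for transcript usage, transcript shares divided by length, and leaving out each library in turn. Those added after the data were seen were a GC and length correction, protein-coding genes alone, leaving out both libraries with RNA of other cells, the share test and its filters, and the block in the list test with an estimated correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.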

Results

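Messenger RNA was sequenced from CD8+ T cells, the killer cells of the adaptive immune system, taken from human blood mononuclear cells. The 12 libraries fell into 3 groups of 4, collected after 48 h. Naive cells received no stimulation. Control cells were stimulated through CD3, part of the T cell receptor complex, and CD28, a co-stimulatory receptor. They also received a scrambled antisense oligonucleotide (ASO), a short synthetic nucleic acid that pairs with RNA. Tra2bPE cells received the same stimulation with an ASO against the poison exon of TRA2B. The labels name no ASO for Naive, and no group was stimulated without an ASO. In comparisons with Naive, the word stimulation therefore covers stimulation together with an ASO. A poison exon holds a premature stop codon, so that a transcript with it is open to nonsense-mediated decay and makes no full-length protein. The total count of replicates 1 to 4 was 288, 298, 400.0 and 518 M in Naive, 389, 406, 428 and 504 M in Control, and 331, 388, 331 and 335 M in Tra2bPE. These are estimated counts on the scale of the quantification program, not read numbers, so floors from a count of 0 describe counting error on that scale alone. The replicates carry numbers from 1 to 4, and nothing in the labels says which of them share a donor, so each p-value measures the spread between these libraries.

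The first question was what the ASO and the stimulation did to TRA2B itself, a splicing factor that binds purine-rich exonic enhancers. TRA2B (ENSG00000136527.19) lies on chromosome 3 of GRCh38 at 185915906 to 185938136, on the minus strand. Its poison exon spans 185931577 to 185931852 (276 bases) in the annotation, between exons at 185937825 to 185938136 and 185926601 to 185926734. The TRA2B level was 86.8 ± 5.85 CPM (counts scaled to a common library size, mean ± SD, n = 4) in Naive, 294 ± 21.1 in Control and 125 ± 10.1 in Tra2bPE. TRA2B was 3.39-fold higher in Control than in Naive (log2 1.76, SE 0.11, edgeR adjusted p = 1.63e-07). With the poison-exon ASO it was 2.36-fold lower than with the scrambled ASO (log2 -1.24, SE 0.11, edgeR adjusted p = 1.71e-04). The 4 libraries of each group did not overlap those of another: Naive lay between 81.7 and 92.8, Tra2bPE between 116 and 139, and Control between 264 and 312 CPM.

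The share of transcripts with the poison exon moved against the level of the gene in both comparisons with Control. These transcripts held 41.0 ± 7.97% of the TRA2B counts in Naive, 16.5 ± 4.63% in Control and 62.6 ± 7.39% in Tra2bPE (SD, n = 4). The share differed by -24.5 percentage points between Control and Naive and by 46.0 points between Tra2bPE and Control, each with p = 0.0286 in an exact two-sided permutation test, the smallest p that 4 samples against 4 can give. Tra2bPE was also above Naive, by 21.5 points (exact permutation p = 0.0286). TRA2B-212 and TRA2B-214, which count toward this share, are annotated as retained introns. Between Naive and Control, shares of retained-intron and decay transcripts were not separated from background, as described below. The poison-exon share in that comparison carries the same limit. Of the 4 annotated transcripts with the full exon, TRA2B-206, annotated as a target of nonsense-mediated decay, held 29.3 ± 10.7% of the gene in Naive, 13.7 ± 4.70% in Control and 57.1 ± 6.60% in Tra2bPE, with exact permutation p = 0.0571 between Control and Naive and p = 0.0286 between Tra2bPE and Control. The full-length coding transcript TRA2B-205 stood at 42.3 ± 7.84 CPM in Naive, 220 ± 15.6 in Control and 39.7 ± 10.02 in Tra2bPE. Its level was thus 5.20-fold higher in Control than in Naive and 5.54-fold lower in Tra2bPE than in Control (exact permutation p = 0.0286 for each), and between Tra2bPE and Naive the exact permutation p was 0.686. The level of TRA2B-206 was 25.05 ± 8.15, 40.7 ± 16.3 and 71.1 ± 9.62 CPM in the same order, with exact permutation p = 0.0857 between Control and Naive and p = 0.0571 between Tra2bPE and Control. Transcript counts were assigned by the quantification program among isoforms that share most of their exons, so a share is an estimate and not a direct count of exon junctions.

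**Figure D1:**
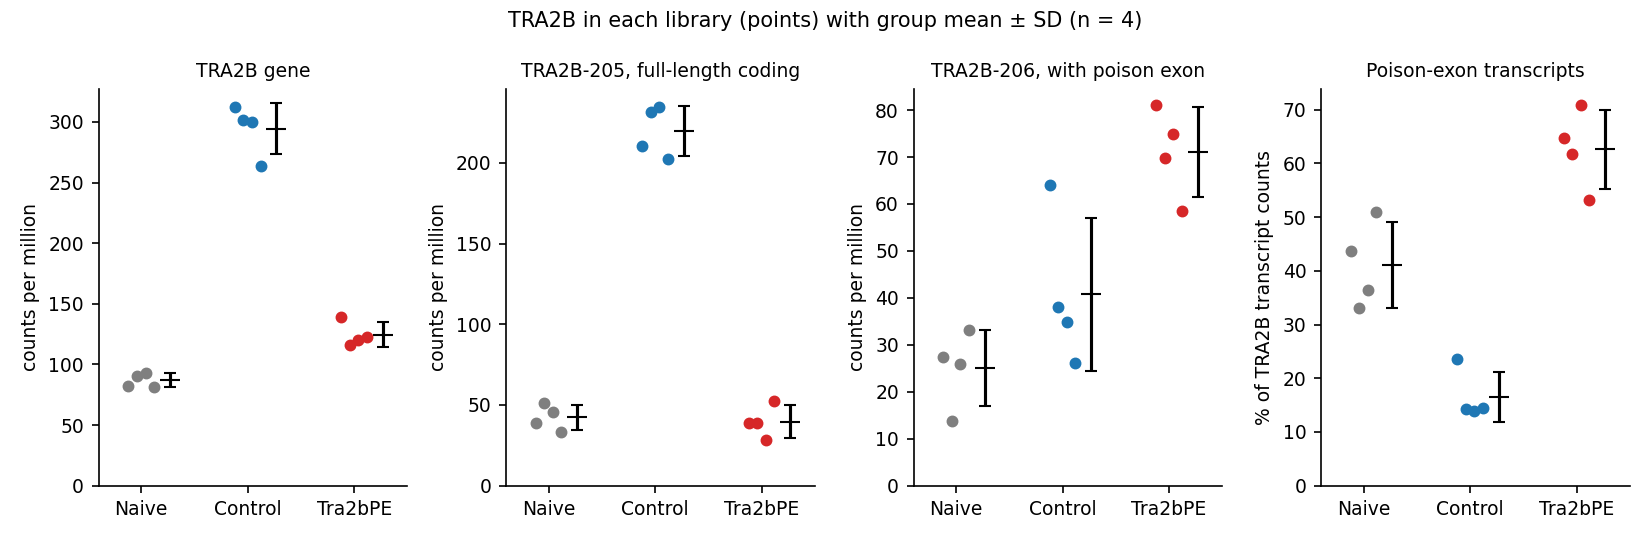
TRA2B gene level, levels of the coding transcript TRA2B-205 and of TRA2B-206 (all in CPM), and the percent of TRA2B counts on poison-exon transcripts, for the 4 libraries of each group (points) with the mean and SD. Control had the highest gene level (294 CPM) and the lowest poison-exon share (16.5%), and Tra2bPE the highest share (62.6%).

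**Figure D2:**
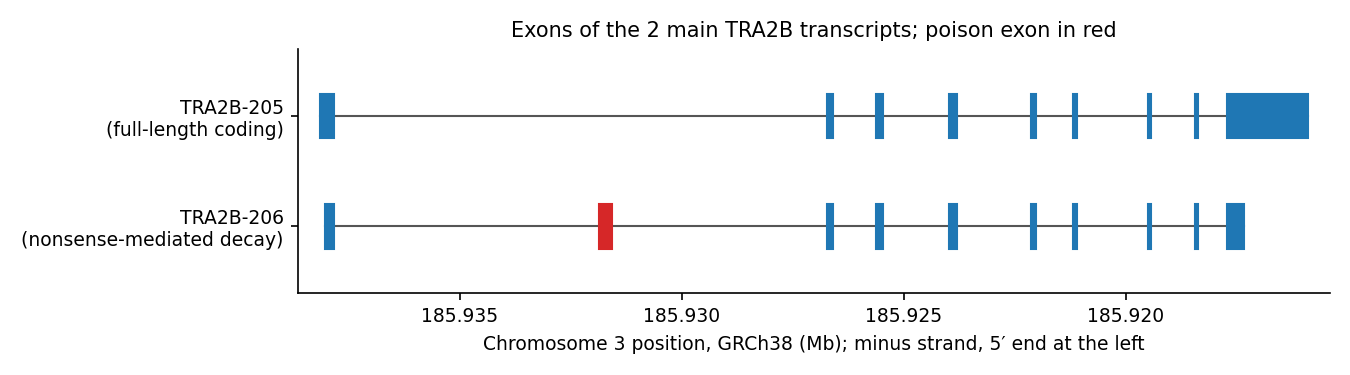
Exons of TRA2B-205 and TRA2B-206 by position on chromosome 3 of GRCh38 (bases), with the poison exon at 185931577 to 185931852 in red. The exon is present in TRA2B-206 and absent from TRA2B-205.

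The comparison of Control with Naive asks how CD8+ T cells respond to stimulation through CD3 and CD28 in the presence of the scrambled ASO. Effects of that ASO cannot be told apart from those of stimulation here. Stimulated cells took on the expression of activated, dividing cells. IL2RA, the high-affinity chain of the interleukin-2 receptor, rose from 3.19 ± 0.707 to 1626 ± 459 CPM, and GZMB, a granule protease that kills target cells, from 287 ± 112 to 17237 ± 5765 CPM (SD, n = 4). IFNG, the cytokine interferon gamma, rose from 1.54 ± 0.204 to 536 ± 278 CPM. KLF2, a transcription factor of resting T cells, fell from 130.0 ± 108 to 1.23 ± 0.653 CPM. The log2 changes were 9.0 (SE 0.34, adjusted p = 1.97e-08), 5.91 (SE 0.56, adjusted p = 3.18e-06), 8.45 (SE 0.64, adjusted p = 5.83e-07) and -6.73 (SE 0.67, adjusted p = 5.31e-06). In all, 14439 of the 29451 genes tested changed, 6917 upward and 7522 downward, and in 49.7% of genes the 4 libraries of one group did not overlap the 4 of the other, where chance gives 2.86%. The balance differed by class: 5215 protein-coding genes rose and 3793 fell, while 1619 genes outside that class rose and 3319 fell.

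All 22 genes of the T cell activation list rose (median log2 change 4.55, camera adjusted p = 4.17e-13, adjusted p = 0.0595 with an estimated correlation), among them the co-stimulatory receptor TNFRSF9, from 5.94 to 739 CPM. Of 27 cytokines and chemokines, 23 rose and 1 fell (median 6.49, or 6.32 with the genes at 0 in Naive set to a floor of 3 counts per library), with adjusted p = 8.47e-12 and adjusted p = 0.0972 with an estimated correlation. IL13 rose by 9.89 on the log2 scale, IL9 by 10.42 and IL3 by 11.51. Of 15 inhibitory receptors, 6 rose and 4 fell, and the list did not pass (adjusted p = 0.327). The checkpoint receptors CTLA4 (from 6.60 to 146 CPM) and LAG3 (from 79.5 to 1350 CPM) were among those that rose. The cytotoxic effector list split, with 6 genes higher and 7 lower of 22 (adjusted p = 0.941). Beside the rise of GZMB stood falls of FGFBP2 (from 114 to 4.66 CPM), CX3CR1 (from 88.0 to 4.09 CPM) and GZMK (from 105 to 11.4 CPM), genes of circulating effector and memory cells. Of the 20 naive and memory genes, 9 fell and 2 rose (median -0.74, adjusted p = 0.0330, adjusted p = 0.403 with an estimated correlation), and this call was lost without Control replicate 4 (adjusted p = 0.0789) or without Naive replicate 3 (adjusted p = 0.0919). TXNIP fell by 4.46 on the log2 scale, the interleukin-7 receptor IL7R by 3.47 and the transcription factor TCF7 by 2.55. Of 14 T cell identity genes, 7 fell and 1 rose (adjusted p = 0.146). For these lists the counts adjusted over the list alone were the same.

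Every gene of the DNA replication list rose (32 of 32, median 4.01, adjusted p = 1.66e-19, adjusted p = 0.103 with an estimated correlation), as did every gene of the mitosis list (30 of 30, median 4.68, adjusted p = 6.41e-14, adjusted p = 0.117 with an estimated correlation). CDC45, a part of the replicative helicase, rose from 0.221 to 117 CPM, the ribonucleotide reductase subunit RRM2 from 0.743 to 185, the mitotic ubiquitin enzyme UBE2C from 0.310 to 106, and BIRC5 from 0.317 to 87.4. The proliferation marker MKI67 rose from 1.71 to 20.3 CPM. MND1 and KIF18B had no counts in Naive and were at least 1489-fold and at least 1109-fold higher in Control, against a floor of 3 counts per library. Of 22 p53 targets, 12 rose and 2 fell, or 3 fell when adjusted over the list alone (median 1.13, adjusted p = 0.00716, adjusted p = 0.30 with an estimated correlation). The cell cycle inhibitor CDKN1A rose by 3.07 and TRIAP1 by 2.52 on the log2 scale. Of 20 apoptosis regulators, 11 rose and 4 fell (median 1.12, adjusted p = 0.00300, adjusted p = 0.0975 with an estimated correlation), with the survival gene BCL2L1 up from 20.6 to 256 CPM.

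The machinery of growth rose with division. All 29 ribosome biogenesis genes rose (median 2.57, adjusted p = 8.28e-19, and 0.0442 with an estimated correlation), BYSL from 7.70 to 168 and NOP16 from 44.9 to 598 CPM. All 36 genes of oxidative phosphorylation rose (median 1.59, adjusted p = 1.99e-15, adjusted p = 0.125 with an estimated correlation), for example the ATP synthase subunit ATP5F1B from 562 to 2939 CPM. Of 20 glycolysis genes, 15 rose and none fell, or 1 fell when adjusted over the list alone (median 2.37, adjusted p = 1.005e-08, adjusted p = 0.117 with an estimated correlation). GAPDH rose from 886 to 10204 CPM, ENO1 from 620 to 6863 and the lactate transporter SLC16A1 from 8.31 to 98.1. Of 44 cytosolic ribosomal protein genes, 28 rose and 1 fell (median 0.95, adjusted p = 4.88e-08, adjusted p = 0.403 with an estimated correlation), among them RPS7 from 181 to 980 CPM. The integrated stress response list, which holds many amino acid synthesis and transport genes, had 19 of 23 genes higher and none lower (median 2.39, adjusted p = 1.43e-09, adjusted p = 0.0773 with an estimated correlation). The amino acid transporter SLC7A5 rose from 19.2 to 1312 CPM and the proline synthesis enzyme PYCR1 from 2.28 to 255. The cholesterol synthesis list had 18 genes higher and 1 lower of 23 (median 1.32, adjusted p = 2.15e-06, adjusted p = 0.117 with an estimated correlation). The unfolded protein response list had 14 of 16 genes higher (median 1.55, adjusted p = 4.75e-06, adjusted p = 0.115 with an estimated correlation), with the chaperone HSPA5 up from 252 to 1487 CPM. Of 20 immediate early and heat shock genes, 15 rose and 2 fell (median 1.49, adjusted p = 2.71e-05, adjusted p = 0.115 with an estimated correlation), for example FOSL1 from 0.390 to 75.1 and HSPD1 from 77.6 to 1061 CPM.

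Splicing genes rose as well. Of 30 core spliceosome genes, 28 rose and 1 fell, or 2 fell when adjusted over the list alone (median 1.63, adjusted p = 1.97e-11, and 0.0223 with an estimated correlation), SNRPD1 from 45.7 to 604 and SNRPB from 201 to 1587 CPM. Of 23 hnRNP genes, which code for RNA-binding proteins that mostly oppose SR proteins, 19 rose and 1 fell, or 20 rose when adjusted over the list alone (median 1.41, adjusted p = 5.44e-08, adjusted p = 0.117 with an estimated correlation). HNRNPAB rose from 50.5 to 700 and HNRNPC from 448 to 1948 CPM. In the list of SR proteins and TRA2, 8 of 14 rose and 2 fell (median 0.86, adjusted p = 0.00588, adjusted p = 0.0972 with an estimated correlation). SRSF1 rose from 40.4 to 223 and SRSF3 from 186 to 820 CPM, while TRA2A, the paralog of TRA2B, stood at 46.8 ± 1.75 and 48.8 ± 5.39 CPM (n = 4, edgeR adjusted p = 0.712). The kinases that phosphorylate SR proteins went the other way, with 8 of 9 lower and 1 higher (median -0.92, adjusted p = 0.0165, adjusted p = 0.256 with an estimated correlation), CLK1 from 243 to 37.7 and CLK4 from 76.3 to 18.7 CPM. Of 14 nonsense-mediated decay genes, 7 rose and 2 fell (median 0.76, adjusted p = 0.0193, adjusted p = 0.103 with an estimated correlation), with the exon junction protein RBM8A up from 125 to 700 CPM.

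Interferon response genes and markers of other blood cells were lower after stimulation, and both moved with Naive replicate 2, a library with 736 CPM of the monocyte gene LYZ against 16.1 to 23.01 in the other Naive libraries. Of 31 interferon response genes, 18 fell and none rose (median -1.26, adjusted p = 0.00975, adjusted p = 0.609 with an estimated correlation), and the call was lost without Naive replicate 2 (adjusted p = 0.0904). XAF1 fell from 73.5 to 10.7 and MX2 from 73.6 to 11.3 CPM. Of 16 monocyte markers, 13 fell, or 14 when adjusted over the list alone (median -5.11, adjusted p = 2.48e-04, adjusted p = 0.30 with an estimated correlation). MS4A7 fell by 8.66 on the log2 scale, and LYZ by 7.53, or by 4.25 without Naive replicate 2. FABP4, a fatty acid binding protein, fell from 18.3 to 0.0167 CPM. Of 12 NK cell markers 6 fell (median -1.83, adjusted p = 0.0269, adjusted p = 0.423 with an estimated correlation), TYROBP from 110 to 3.65 and KLRF1 from 12.2 to 0.170 CPM. Of 13 B cell markers 7 fell (median -2.10, adjusted p = 0.0273, adjusted p = 0.349 with an estimated correlation), a call lost without Naive replicate 2 (adjusted p = 0.0744). Of 9 markers of gamma delta and invariant T cells 7 fell (median -2.19, adjusted p = 0.0170, adjusted p = 0.400 with an estimated correlation).

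The other lists did not pass. In the CD4 T cell list 2 genes rose and 4 fell of 11 (median -0.40, mean -0.00, adjusted p = 0.947 in the upward direction). In the dendritic cell list 1 rose and 2 fell of 7 (median 0.10, mean -2.33, adjusted p = 0.668). In the platelet and red cell list 1 of 9 fell (adjusted p = 0.335), and of 13 mitochondrially encoded genes 2 fell (adjusted p = 0.561), while adjusted over the list alone neither had a gene that fell. Control replicate 4 held transcripts of connective tissue cells. COL1A2, a collagen chain, was at 618 CPM there and at 0.192 to 0.898 CPM in the other Control libraries, so its log2 change of 11.01 was 2.59 without that library, and its call was lost with limma-voom (adjusted p = 0.233). PLOD2, a collagen-modifying enzyme at 0 in Naive, was at 24.0 CPM there and at 0.104 to 0.701 CPM in the other Control libraries, and its call was lost with limma-voom (adjusted p = 0.0507).

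Genes were tested with the edgeR quasi-likelihood test and lists with camera at a preset correlation, which called 25 of 32 lists. With an estimated correlation 2 lists held, core spliceosome and ribosome biogenesis. The median log2 change of all genes tested was -0.31, and it moved by -0.10 with a correction for GC content and length and by -0.22 when protein-coding genes alone were scaled and tested.

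The comparison of Tra2bPE with Control asks what the poison-exon ASO changed in stimulated cells. At the preset correlation of the list test, genes of DNA replication, mitosis, glycolysis, hnRNP proteins and the core spliceosome were lower and interferon response genes higher with the ASO, and with an estimated correlation 0 of 32 lists passed. MCM2, a part of the replicative helicase, fell from 494 ± 34.6 to 100.1 ± 53.1 CPM, and GZMB from 17237 ± 5765 to 3578 ± 2328 CPM (SD, n = 4). SLC16A1 fell from 98.1 ± 9.59 to 24.6 ± 6.10 CPM. IFIT2, an antiviral protein induced by interferon, rose from 2.998 ± 0.495 to 43.3 ± 9.30 CPM. The log2 changes were -2.30 (SE 0.36, adjusted p = 0.00150), -2.27 (SE 0.47, adjusted p = 0.00624), -2.0 (SE 0.22, adjusted p = 3.78e-04) and 3.85 (SE 0.38, adjusted p = 2.74e-04). In all, 5932 of 29451 genes changed, 3055 upward and 2877 downward, and in 25.7% of genes the groups did not overlap, where chance gives 2.86%. Without Tra2bPE replicate 1 the count was 3940, and without Tra2bPE replicate 3 it was 3818.

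**Figure D3:**
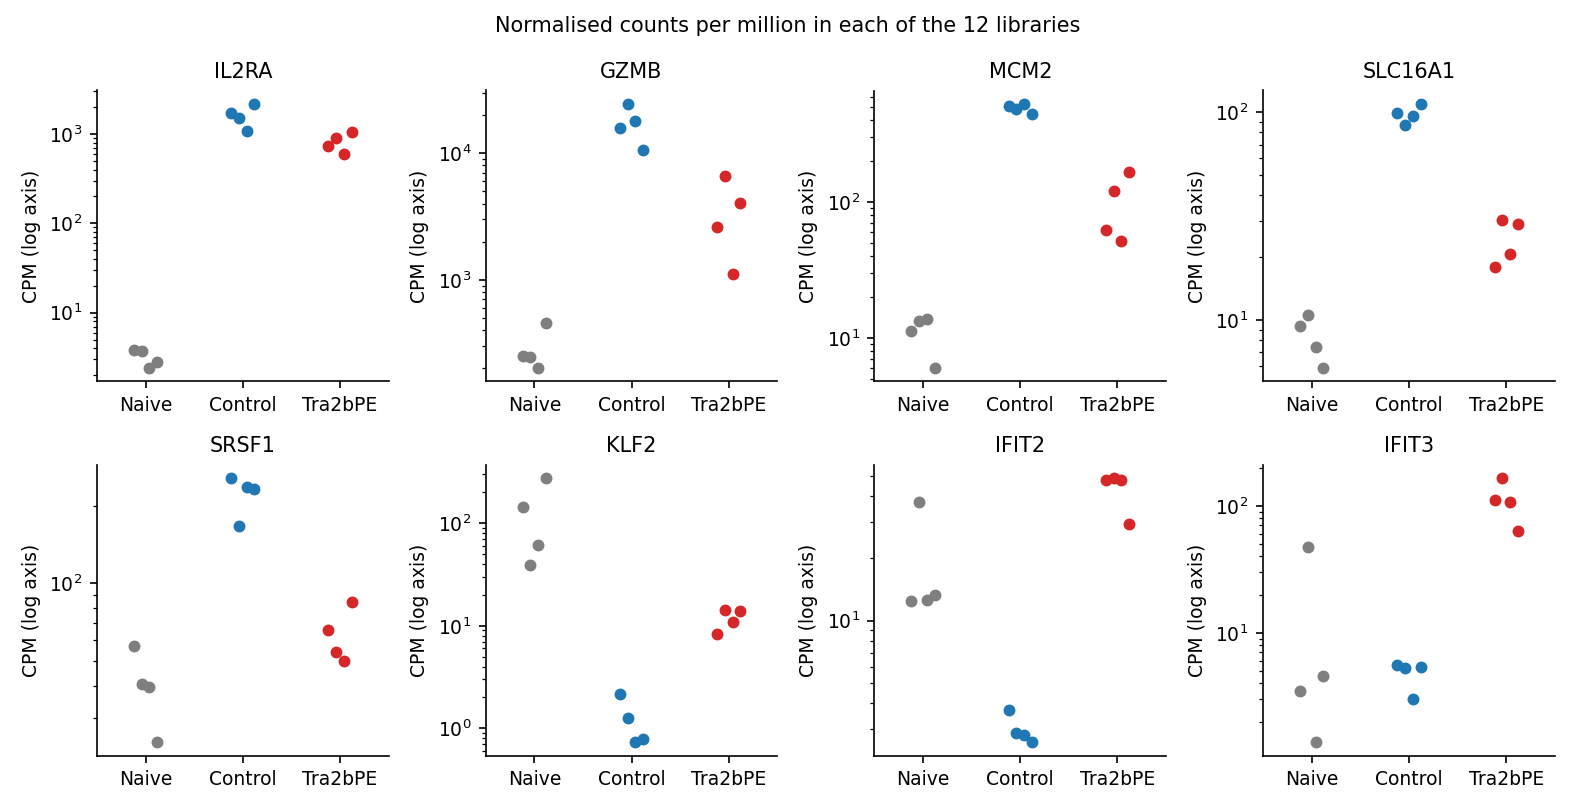
Levels of 8 genes (CPM, log axis) in the 4 libraries of each group (points). The ASO group lay below Control for IL2RA, GZMB, MCM2, SLC16A1 and SRSF1 and above it for KLF2, IFIT2 and IFIT3.

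Of 32 DNA replication genes, 28 fell with the ASO, and all 32 when adjusted over the list alone (median -1.69, adjusted p = 7.89e-21, adjusted p = 0.161 with an estimated correlation). UHRF1, which maintains DNA methylation at replication forks, fell from 418 to 52.9 CPM, and TYMS, the enzyme of thymidylate synthesis, from 159 to 29.2. Of 30 mitosis genes, 11 fell, or 17 when adjusted over the list alone (median -1.46, adjusted p = 7.48e-10, adjusted p = 0.309 with an estimated correlation). CCNA2 (cyclin A) fell from 54.3 to 11.1 CPM and the checkpoint kinase BUB1B from 13.8 to 2.62, while MKI67 was at 20.3 ± 6.22 and 12.7 ± 7.94 CPM (n = 4, edgeR adjusted p = 0.555). Of 22 p53 targets, 6 rose, or 7 when adjusted over the list alone (median 0.28, adjusted p = 0.0296, adjusted p = 0.591 with an estimated correlation). This ASO call was lost without Control replicate 2 (adjusted p = 0.0506), Control replicate 3 (adjusted p = 0.0517) or Tra2bPE replicate 3 (adjusted p = 0.0862). The apoptosis inducer BBC3 rose from 7.48 to 21.1 CPM and ZMAT3 from 14.3 to 36.8, while CDKN1A was at 81.8 ± 53.6 and 85.2 ± 29.3 CPM (n = 4, edgeR adjusted p = 0.958). In the apoptosis list 4 genes rose and 3 fell of 20, or 4 fell when adjusted over the list alone (median -0.14, mean 0.00, adjusted p = 0.424), with BMF higher (7.21 against 1.66 CPM).

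Among T cell genes, 6 of 22 activation genes fell and 1 rose, or 8 fell when adjusted over the list alone (median -0.61, adjusted p = 0.0261, adjusted p = 0.591 with an estimated correlation). This ASO call was lost without Tra2bPE replicate 3 (adjusted p = 0.0507). IL2RA fell from 1626 to 816 CPM (log2 -0.99, adjusted p = 0.0137), TNFRSF8 from 17.2 to 1.97, the transferrin receptor TFRC from 252 to 82.4 and ICOS from 87.5 to 32.9. In the cytotoxic list 6 of 22 fell and 1 rose, or 8 fell when adjusted over the list alone (median -0.70, adjusted p = 0.0296, adjusted p = 0.613 with an estimated correlation). That call was lost without Control replicate 1 (adjusted p = 0.0831), Control replicate 2 (adjusted p = 0.0506) or Tra2bPE replicate 3 (adjusted p = 0.146). GZMA fell from 134 to 24.0 and the granule membrane protein LAMP1 from 65.3 to 22.9 CPM. Of 27 cytokines and chemokines 2 rose and 3 fell, or 4 fell when adjusted over the list alone (median -0.78, adjusted p = 0.0296, adjusted p = 0.591 with an estimated correlation), a call lost without Control replicate 2 (adjusted p = 0.0608) or Tra2bPE replicate 3 (adjusted p = 0.128). IL2 rose from 8.48 to 51.2 CPM and CXCL8 from 9.46 to 48.2.

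IFNG was at 536 ± 278 CPM in Control and 253 ± 147 in Tra2bPE (n = 4, edgeR adjusted p = 0.120, 0.0276 without Control replicate 3, 0.0412 without Tra2bPE replicate 4, 0.0401 with the DESeq2 Wald test and 0.0267 with the GC and length correction and the replicate number as a block). In the naive and memory list 4 rose and 4 fell of 20, or 5 fell when adjusted over the list alone (adjusted p = 0.440). KLF2 rose from 1.23 to 11.9 CPM, TXNIP from 75.4 to 223 and IL7R from 66.8 to 157. TCF7 was at 51.7 ± 21.7 and 85.6 ± 21.9 CPM (n = 4, edgeR adjusted p = 0.101, 0.0351 without Control replicate 3, 0.0462 with the stricter filter, 0.0475 with protein-coding genes alone and 0.0295 with the replicate number as a block). In the T cell identity list 5 of 14 fell and 2 rose, or 6 fell when adjusted over the list alone (adjusted p = 0.146, and 0.0390 in the ASO comparison without Control replicate 4), with CD8A down from 592 to 212 and the kinase ZAP70 from 238 to 133 CPM.

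Of 15 inhibitory receptors 2 fell, or 1 when adjusted over the list alone (adjusted p = 0.230). CTLA4 fell from 146 to 36.6 CPM (adjusted p = 0.0191), a call lost without Control replicate 2 (0.0520), Tra2bPE replicate 1 (0.0635) or Tra2bPE replicate 3 (0.0569). LAG3 fell from 1350 to 481 CPM (adjusted p = 0.0387), a call lost without Control replicate 1 (0.0887), Control replicate 2 (0.101), Control replicate 4 (0.0554), Tra2bPE replicate 1 (0.0878), Tra2bPE replicate 3 (0.0740) or Tra2bPE replicate 4 (0.0583), and with upper-quartile scaling (0.0527) or no filter (0.0589).

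RNA processing genes other than TRA2B also moved. Of 23 hnRNP genes 15 fell and none rose, or 19 fell when adjusted over the list alone (median -0.83, adjusted p = 6.23e-11, adjusted p = 0.161 with an estimated correlation), HNRNPAB from 700 to 219 and HNRNPU from 724 to 359 CPM. Of 30 core spliceosome genes 10 fell, or 14 when adjusted over the list alone (median -0.41, adjusted p = 1.17e-05, adjusted p = 0.161 with an estimated correlation), PRPF19 from 108 to 46.3 and SF3A1 from 159 to 80.1 CPM. In the list of SR proteins and TRA2, 3 fell and 1 rose of 14, or 4 fell and 2 rose when adjusted over the list alone (adjusted p = 0.0635). In this ASO comparison the list passed with DESeq2 size factors (adjusted p = 0.0402) and without Control replicate 4 (adjusted p = 0.0381). TRA2B, SRSF1 (from 223 to 63.5 CPM) and SRSF9 (from 684 to 420.5) fell and SRSF11 (from 233 to 340) rose. TRA2A was at 48.8 ± 5.39 and 61.2 ± 7.05 CPM (n = 4, edgeR adjusted p = 0.0831, and 0.0330 without Tra2bPE replicate 2, 0.0279 with upper-quartile scaling, 0.0265 with the stricter filter and 0.0172 with protein-coding genes alone). Of 9 SR protein kinases 5 rose and 1 fell, or 2 fell when adjusted over the list alone (adjusted p = 0.121), with CLK1 up from 37.7 to 98.6, DYRK1A from 5.38 to 14.5 and PRPF4B from 35.1 to 78.2 CPM. In the nonsense-mediated decay list 4 rose and 2 fell of 14, or 3 fell when adjusted over the list alone (median -0.11, mean 0.08, adjusted p = 0.990). UPF3B rose from 31.4 to 73.7 and UPF2 from 33.8 to 74.0 CPM, while SMG5 fell from 182 to 105.

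Among metabolic and growth genes, 5 lists were lower at the preset correlation and the others did not pass. Of 20 glycolysis genes 17 fell, or 18 when adjusted over the list alone (median -1.08, adjusted p = 4.26e-13, adjusted p = 0.161 with an estimated correlation), with HK1 down from 322 to 103 and PGAM1 from 1279 to 469 CPM. Of 36 genes of oxidative phosphorylation 8 fell, or 10 when adjusted over the list alone (median -0.33, adjusted p = 7.28e-04, adjusted p = 0.591 with an estimated correlation), among them ATP5PB from 425 to 238 CPM. Of 29 ribosome biogenesis genes 17 fell, or 21 fell and 1 rose when adjusted over the list alone (median -0.60, adjusted p = 6.07e-08, adjusted p = 0.169 with an estimated correlation), POLR1B from 96.2 to 42.4 and TSR1 from 206 to 98.8 CPM. Of 44 cytosolic ribosomal protein genes 2 rose (adjusted p = 0.660, and 0.0358 in the ASO comparison without Control replicate 3). Of 23 cholesterol synthesis genes 12 fell and 1 rose, or 18 fell when adjusted over the list alone (median -0.73, adjusted p = 6.09e-07, adjusted p = 0.198 with an estimated correlation). HMGCS1 fell from 36.9 to 13.4 CPM, and INSIG1, which holds back sterol synthesis, rose from 60.9 to 225. Of 16 unfolded protein response genes 10 fell, or 12 when adjusted over the list alone (median -0.99, adjusted p = 9.53e-08, adjusted p = 0.161 with an estimated correlation), PDIA4 from 294 to 83.6 and CANX from 364 to 108 CPM. The integrated stress response list split, with 5 of 23 higher and 7 lower, or 8 lower when adjusted over the list alone (adjusted p = 0.218). PPP1R15A rose from 88.5 to 318 CPM, while DDIT4 fell from 565 to 171 and SLC7A5 from 1312 to 420.1. Of 20 immediate early and heat shock genes 1 rose and 5 fell, or 4 rose and 7 fell when adjusted over the list alone (adjusted p = 0.149), with HSPD1 down from 1061 to 516 CPM. None of 13 mitochondrially encoded genes changed (adjusted p = 0.414).

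Interferon response genes were higher with the ASO. Of 31, 24 rose and none fell, or 28 rose when adjusted over the list alone (median 2.04, adjusted p = 5.35e-13, adjusted p = 0.298 with an estimated correlation). IFIT3 rose from 4.80 to 111 CPM, IFIT1 from 1.24 to 28.1 and XAF1 from 10.7 to 107. Monocyte markers were higher too, with 5 higher and 1 lower of 16, or 8 higher and 2 lower when adjusted over the list alone (median 2.20, adjusted p = 0.0133, adjusted p = 0.591 with an estimated correlation), a call lost in the ASO comparison without Tra2bPE replicate 2 (adjusted p = 0.0712). S100A9 rose from 3.52 to 51.2 CPM, and the chemokine CCL2, which monocytes also make, from 11.3 to 171. TGM1, a transglutaminase, rose from 0.521 to 10.3 CPM. Of 13 B cell markers 2 fell (median -0.82, adjusted p = 0.0212, adjusted p = 0.477 with an estimated correlation). The remaining lists did not pass: 1 of 12 NK cell markers rose (TYROBP, from 3.65 to 22.6 CPM; adjusted p = 0.756), 2 of 9 gamma delta and invariant T cell markers rose (adjusted p = 0.675, with 1 that fell when adjusted over the list alone), 2 of 7 dendritic cell markers rose (adjusted p = 0.289, with 1 that fell when adjusted over the list alone), 1 of 9 platelet and red cell markers rose (adjusted p = 0.266), and 2 of 11 CD4 T cell markers fell, or 3 when adjusted over the list alone (adjusted p = 0.149, and 0.0341 without Control replicate 3).

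Among the largest falls were genes that moved with Control replicate 4, the library with connective tissue transcripts. PLOD2 fell by 8.21 on the log2 scale (adjusted p = 0.0300), but without that library the change was -4.02 (adjusted p = 0.121), and without any one of the Tra2bPE libraries the adjusted p of PLOD2 lay between 0.0606 and 0.0762, and with limma-voom it was 0.188. COL6A3 fell by 4.21 (adjusted p = 0.0328), with a change of -2.90 and adjusted p = 0.0968 without Control replicate 4. The adjusted p of COL6A3 was 0.0503 without Control replicate 1 and 0.0883, 0.0526 and 0.0689 without Tra2bPE replicate 1, 3 or 4, and 0.0570 with the replicate number as a block. IGF2 fell by 4.09 (adjusted p = 0.0229), with a change of -2.11 and adjusted p = 0.113 without Control replicate 4, adjusted p = 0.0648, 0.0696 and 0.0567 without Tra2bPE replicate 1, 3 or 4, adjusted p = 0.0571 with limma-voom and adjusted p = 0.0821 with the replicate number as a block. FLT1 (from 9.44 to 0.634 CPM) and PTGIS (from 6.78 to 0.224) fell and kept their call whichever library was left out.

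**Figure D4:**
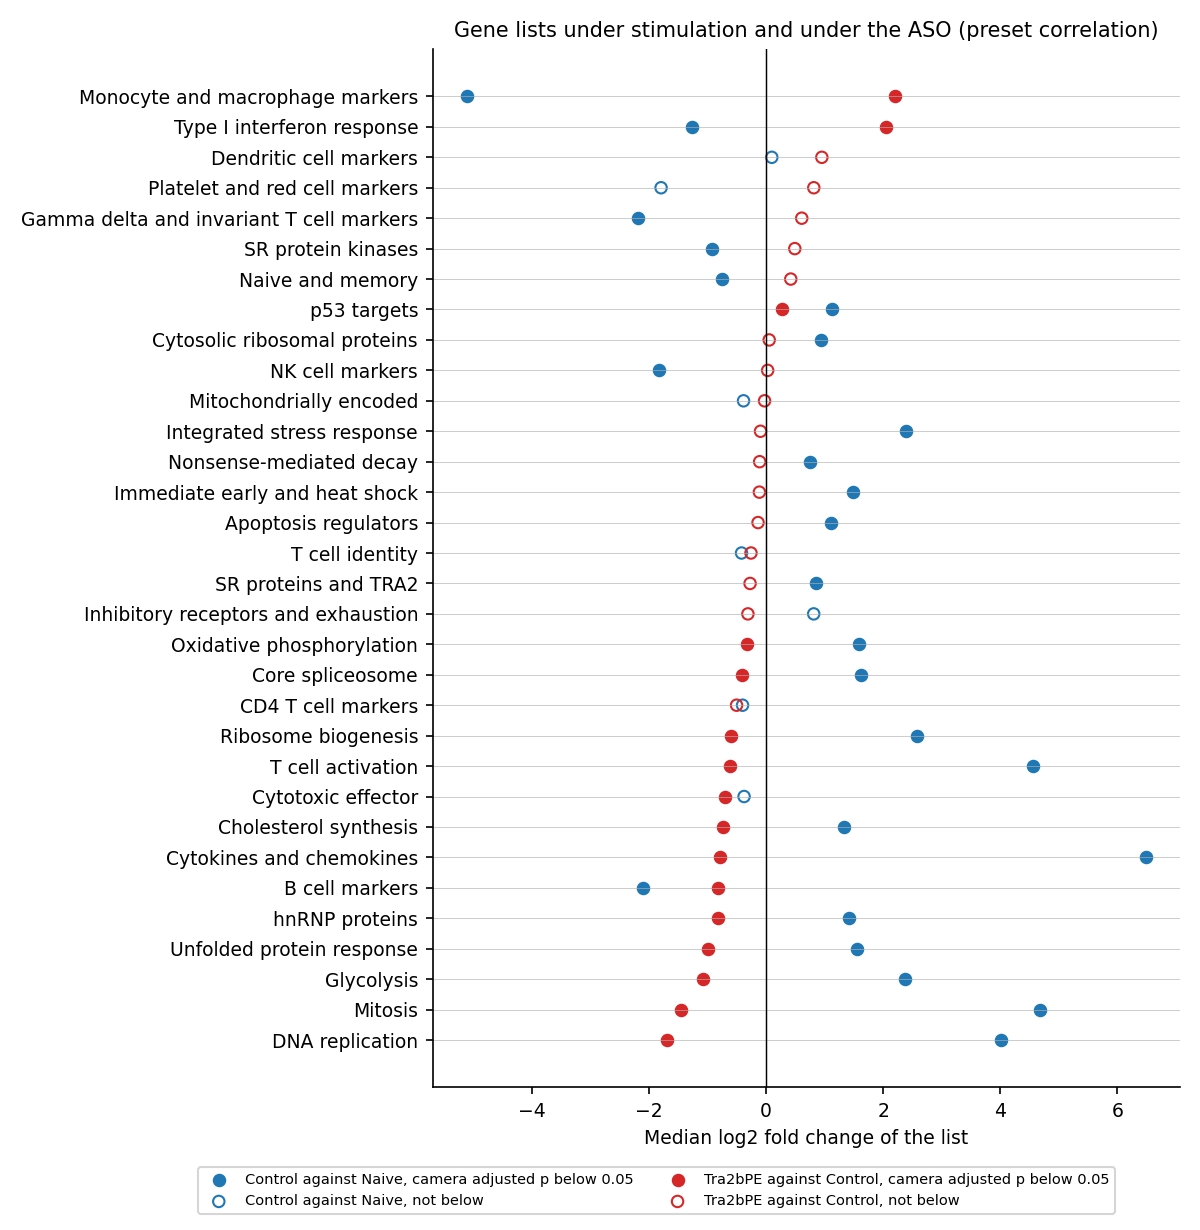
Median log2 fold change of each of the 32 gene lists for stimulation (Control minus Naive) and for the ASO (Tra2bPE minus Control), with filled points where the camera adjusted p was below 0.05. The interferon list moved from -1.26 to 2.04 between the comparisons, and the DNA replication list from 4.01 to -1.69.

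Among genes outside the protein-coding class, 1319 rose and 222 fell with the ASO of 12626 tested (median log2 change 0.48), against 1562 and 2639 of 15585 protein-coding genes (median -0.13). Noncoding genes held 8.94 ± 0.944% of the counts in Naive, 3.72 ± 0.0999% in Control and 6.03 ± 0.953% in Tra2bPE (SD, n = 4). Camera at the preset correlation called 16 of 32 lists, 3 higher and 13 lower (fry called 12). The share of changed genes that were higher was 51.5%, 62.9% with upper-quartile scaling, 45.6% with DESeq2 size factors and 44.1% with the GC and length correction, so the scaling decided which direction held more genes. Among the 3552 genes changed at least 2-fold, 2317 were higher and 1235 lower. Upper-quartile scaling moved the median of all genes by 0.13, and protein-coding genes alone moved it by 0.14. The median of every list called here lay farther from 0 than either shift.

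The comparison of Tra2bPE with Naive asks how far cells with the poison-exon ASO still responded to stimulation. They responded broadly, with 10035 of 29451 genes changed, 5633 upward and 4402 downward, and with the 2 groups apart in 37.2% of genes where chance gives 2.86%. The median of all genes was -0.10 and moved by -0.21 with the GC and length correction, under which 5227 genes rose and 5267 fell. IL2RA stood at 816 ± 199 CPM against 3.19 ± 0.707 in Naive (log2 8.0, adjusted p = 4.99e-08), GZMB was 3.64 higher on the log2 scale, IFNG 7.36, CDC45 7.31, CDKN1A 3.13 and MKI67 2.89. KLF2 fell by 3.45, TXNIP by 2.89 and TCF7 by 1.83. TRA2B was 0.52 higher on the log2 scale (adjusted p = 0.00227). TRA2A was 0.39 higher (adjusted p = 0.0290), a call lost without Naive replicate 1, 2 or 3 (adjusted p = 0.0644, 0.0647 and 0.0593) or Tra2bPE replicate 1, 3 or 4 (0.0872, 0.0862 and 0.0717). The TRA2A call was also lost with no filter (0.0658), the stricter filter (0.0514), protein-coding genes alone (0.0669) and the GC and length correction (a change of 0.06, adjusted p = 0.757). Of the 31 interferon genes 7 rose and 2 fell, or 14 rose when adjusted over the list alone (median 0.95, adjusted p = 0.00129, adjusted p = 0.492 with an estimated correlation), with ISG15 up from 167 to 831 CPM. Of the 16 monocyte markers 7 fell, or 9 when adjusted over the list alone (median -3.60, adjusted p = 0.00643, adjusted p = 0.397 with an estimated correlation). Of the 32 lists, 26 were called with the preset correlation and 5 with an estimated one, namely T cell activation, core spliceosome, nonsense-mediated decay, ribosome biogenesis and the integrated stress response.

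Set side by side, the changes by the ASO ran mostly against those by stimulation. Of the 4813 genes that changed in both, 4584 changed in opposite directions, 2180 of them up with stimulation and down with the ASO and 2404 the other way, where independent calls would give 676 and 780. Both comparisons use the Control libraries, which alone makes the changes oppose each other: across genes r was -0.60, and in simulated data with no change it was -0.50. The covariance, -2.42, was -0.34 in those simulations. They gave no gene called in both, but no gene was changed in them. They therefore cannot show how many opposite calls the shared libraries make among genes that respond. With the Control libraries divided between the comparisons, 2 in each, r was -0.28 and the covariance -1.94 as means over 6 divisions. Genes are not independent replicates, so these are descriptions across genes.

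Transcript shares within genes were compared because TRA2B is a splicing factor. The test planned before the data were examined, diffSpliceDGE in edgeR, called 1381 of 10919 genes for stimulation and 583 for the ASO, but other divisions of the same libraries gave up to 228 and 381 calls, and on simulated data it recovered 2% of 2-fold changes. A limma test of the shares themselves, chosen after this was seen, called 3507 of 7305 genes for stimulation and 756 for the ASO, with at most 4 and 5 calls in other divisions, and its genes are described here. With the replicate number as a block it called 377 for the ASO. On the same simulated data it recovered 0% of 2-fold and of 4-fold changes with 0 false calls. TRA2B was among them (adjusted p = 0.00505 for stimulation and 0.00244 for the ASO), while the planned test called TRA2B for the ASO (adjusted p = 2.01e-05) and not for stimulation (adjusted p = 0.224). For the ASO, 140 transcripts annotated for nonsense-mediated decay rose in share and 26 fell, and 180 with a retained intron rose and 24 fell, against 284 and 400 protein-coding transcripts. With stimulation the counts were 194 decay transcripts higher and 571 lower and 122 retained-intron transcripts higher and 2122 lower. Of the 756 genes called for the ASO, 592 were also called for stimulation, where independent calls would give 363. Of the 822 transcripts called in both, 790 changed in opposite directions, in comparisons that share the Control libraries. Share changes by lower TRA2B were thus not told apart from a reversal of the stimulation change.

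Splicing genes were overrepresented among the genes with changed shares under the ASO, with 13 of the 53 tested (24.5% against 10.3% of all genes, two-sided Fisher's exact p = 0.00234), and not significantly under stimulation (60.4% against 48.0%, Fisher's exact p = 0.0741). This set joined the SR and TRA2, hnRNP, core spliceosome and SR protein kinase lists and was put together with the added share test. TRA2B, the target of the ASO, was among the 13. Genes were not matched for level or number of transcripts. SAFB, a scaffold attachment factor named by its planned p-value, raised the share of its decay transcript SAFB-207 from 2.75 ± 0.751 to 14.7 ± 2.43% with the ASO (SD, n = 4, limma adjusted p = 0.00399). The following transcripts were picked after their values were seen. The decay transcript SRSF3-203 held 30.9 ± 7.44% of SRSF3 in Naive, 4.83 ± 0.962% in Control and 25.6 ± 7.31% in Tra2bPE. In the same groups SRSF2-204 held 38.2, 17.0 and 36.8% of SRSF2, U2AF1-206 held 21.0, 9.02 and 22.4% of U2AF1, and HNRNPM-214 held 41.2, 6.30 and 35.5% of HNRNPM. Each was lowest in Control. The summed share of decay transcripts, tested over 28 genes of the SR, hnRNP and core spliceosome lists by exact permutation, passed for 0 of them in either comparison after adjustment (11 had an unadjusted p below 0.05 for stimulation and 13 for the ASO), a test that can hardly pass since its smallest p is 0.0286. With the ASO it was higher in 10 and lower in 1 of the SR genes, higher in 6 and lower in 4 of the hnRNP genes, and higher in 6 and lower in 1 of the core spliceosome genes. HNRNPU-208 rose from 2.67 to 15.6% of HNRNPU with the ASO, and SNRNP70-202 fell from 37.0 to 3.90% of SNRNP70 with stimulation. Under stimulation RUNX3, a transcription factor of CD8+ T cells named by its planned p-value, shifted between coding transcripts, with RUNX3-203 up from 13.8 to 53.3% and RUNX3-201 down from 85.6 to 38.2%. With the ASO SRP14-208, also named by its planned p-value, rose from 0.0262 to 4.67% of SRP14.

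Over all protein-coding genes, decay transcripts held 5.11 ± 0.302% of counts in Naive, 3.72 ± 0.125% in Control and 4.57 ± 0.400% in Tra2bPE, and retained-intron transcripts 8.99 ± 0.540, 5.36 ± 0.145 and 6.50 ± 0.547% (SD, n = 4). Control differed from both other groups in each class (exact two-sided permutation p = 0.0286, adjusted over 15 tests 0.0357), and between Tra2bPE and Naive the retained-intron class differed as well (exact permutation p = 0.0286, adjusted 0.0357), while the decay class gave an exact permutation p of 0.0857. Counts on olfactory receptor genes, a measure of background from genomic DNA, ran with the difference between Naive and Control. Summed over 381 such genes, they were 23.01 ± 0.643, 5.39 ± 1.21 and 4.74 ± 1.53 CPM without TMM scaling in Naive, Control and Tra2bPE (SD, n = 4). Unspliced RNA of expressed genes was not measured by them, and the part of such background in the shares was not tested. The lower shares of decay and retained-intron transcripts after stimulation were not separated from that background. Of the 10 genes with the smallest planned p-values, 10 passed the limma test for stimulation and 3 for the ASO.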

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

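The interferon tests of scaling and of monocyte RNA, and the other divisions of the libraries for the added share test, were chosen only after the results were seen, the scope of the test of RNA from other cells for the noncoding genes was narrowed to Control replicate 4, and the count of connective tissue markers was changed from filtered genes to all genes after a first form had given 12 of 13. A library was picked out when its gap to the nearest of the other 3 of its group, divided by the range of the group, was above Dixon's critical value. Chance picks about 1 in 20 groups, which for the 408 groups tested is 20.4, and 28 were found. Of these, 7 were in Naive replicate 2, 4 each in Control replicate 4 and Naive replicate 4, and 3 in Control replicate 3.

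In Naive replicate 2 LYZ was at 736 CPM (the others 16.1 to 23.01), CCL2 at 98.1 (5.01 to 10.4), S100A9 at 53.6 (3.59 to 6.85), XAF1 at 159 (31.7 to 51.9), IFIT1 at 38.1 (3.82 to 7.72), IFIT2 at 37.1 (12.4 to 13.3) and IFIT3 at 47.0 (1.37 to 4.57). In Control replicate 4 COL1A2 was at 618 CPM (0.192 to 0.898), IGF2 at 54.6 (1.67 to 7.27) and PLOD2 at 24.0 (0.104 to 0.701), and HNRNPM-214 held 12.2% of HNRNPM (3.45 to 4.86%). In Naive replicate 4 HSPD1 was at 57.9 CPM (83.0 to 86.2), POLR1B at 17.7 (26.9 to 27.5), SRSF3 at 171 (190 to 193) and PTGIS at 0.00647 (0 in the others). In Control replicate 3 IFIT3 was at 2.99 CPM (5.26 to 5.54) and SRSF11 at 214 (238 to 241), and retained-intron transcripts held 5.58% of counts (5.27 to 5.31%).

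In Control replicate 1 the poison-exon transcripts held 23.5% of the TRA2B counts (13.97 to 14.5% in the others) and TRA2B-205 held 67.5% (76.7 to 78.3%). In Naive replicate 3 ATP5F1B was at 664 CPM (513 to 537) and CD8A at 431 (532 to 533). In Tra2bPE replicate 2 the total was 388 M (331 to 335) and IL9 was at 21.7 CPM (0.389 to 1.40). In Tra2bPE replicate 4 IFIT2 was at 29.4 CPM (47.5 to 48.7) and TFRC at 139 (58.6 to 68.4). CCNA2 was at 0.579 CPM in Naive replicate 1 (0.936 to 0.949), and SMG5 at 155 in Control replicate 2 (190 to 192).

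Interferon response genes were higher in Tra2bPE than in Control. Scaling between libraries was argued against by a median that was 1.98 at the lowest of 5 scalings, and a single library by a lowest median of 2.03 with 1 library left out. Monocyte markers had a median of 2.20 in the same comparison, and genes of both sets were high in Naive replicate 2. A larger amount of monocyte RNA, with the interferon genes per monocyte as in Naive, was argued against as the whole cause by monocyte markers whose median, Tra2bPE minus Naive, was -3.60 while that of the interferon genes was 0.95 (adjusted p = 0.492 with an estimated correlation). A changed state of the monocytes present, a reaction to the sequence or chemistry of the ASO, and an effect of lower TRA2B all stayed open, since 1 ASO was compared with 1 scrambled ASO.

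Many genes of connective tissue were highest in Control replicate 4. RNA of stromal cells in the library fitted: 17 of 18 marker genes chosen before their values were seen were highest there, with a median of 21.97 times the next library. A response to stimulation was argued against by a median level in the other Control libraries of 0.00207 of that in replicate 4. Where the cells came from was not tested, and no biological explanation for them was tested.

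Noncoding genes were higher in Tra2bPE than in Control, by a median log2 change of 0.62 above that of protein-coding genes. GC content and length bias as the whole cause was argued against by a difference that stayed at 0.39 with that correction, and the stromal RNA of Control replicate 4 by one of 0.58 without that library and Naive replicate 2. Carry-over of genomic DNA was argued against by olfactory receptor genes, at 0.880 times the Control level in Tra2bPE where the noncoding share needed 1.62. RNA of monocytes, whose markers were higher in Tra2bPE, a lower rate of decay of such RNA and a weaker response to stimulation stayed open, and none of them was tested.

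The libraries of each comparison were divided in 35 ways, the real one included. The replicate number was ignored, so what follows holds only if the numbers do not mark pairs. For the gene counts only 1 of the 35 divisions, the real one, gave as many: 14439, 5932 and 10035 against at most 2, 1 and 0 in another. That rank is the most that 35 divisions can show. Every other division mixed the 2 groups, which widens the spread within each side, so low counts there were likely in advance. If the numbers mark pairs, the smallest exact p is 0.125, and chance is not excluded. In the share test the real count was the largest as well (3507 against 4 and 756 against 5). That test was added after the planned one had given many calls in these same divisions, so its rank is not independent evidence. For transcript usage as planned the real count was the largest (1381 against 228 for stimulation and 583 against 381 for the ASO). That ranks the count alone: with 381 calls in another division, many of the 583 may be false. For the lists the real count was the largest for stimulation (25 against 23) and for Tra2bPE against Naive (26 against 24), each by a small margin. Chance cannot be excluded for the number of lists called with the ASO (16 against 18), where 4 divisions, the real one included, gave as many. The other divisions with as many lists kept 3 of the 4 libraries of each group together and so carried part of the real difference, and divisions with 2 and 2 gave at most 11.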

How the results depend on the processing

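The alternatives added after the data were seen were the GC and length correction, protein-coding genes alone, leaving out Control replicate 4 with Naive replicate 2, the limma share tests and the block with an estimated correlation. In the gene tests the level of TRA2B kept its direction and its call in every setting. That does not cover its transcript shares, where the planned diffSpliceDGE test did not call TRA2B for stimulation (adjusted p = 0.224). Gene counts stayed within 1.5 times except for stimulation with protein-coding genes alone (9067, fewer genes tested) and for the ASO with a minimum fold change of 2 (3552, a stricter call) or without Tra2bPE replicate 1 or 3. Leaving out each library gave 13141 to 14220 genes for stimulation, 3818 to 5556 for the ASO and 8662 to 9333 for Tra2bPE against Naive, 23 to 25, 12 to 18 and 24 to 26 lists, a TRA2B change of 1.69 to 1.80 and of -1.29 to -1.20, a poison-exon share difference of -27.1 to -21.2 and of 43.3 to 49.2 points, and 1112 to 1373 and 522 to 634 genes by the planned transcript test. With transcripts divided by their length the share differences were -28.5 and 49.3 points. An estimated correlation in camera left 2, 0 and 5 lists. The planned transcript test gave 695 and 168 genes (stimulation, ASO) with a stricter filter and 470 and 92 with transcripts of 5 percent of their gene (both test fewer transcripts). The gene-level F test gave 3910 and 1390, and limma-voom diffSplice 4011 and 1297, and the cause was not tested. The limma share test gave 3507 and 756 with 1 CPM in 4 samples, 2539 and 326 with the 5 percent filter, and 4785 and 852 with filterByExpr, and the cause was not tested. Over at most 20 settings each, 57 genes named for stimulation kept direction and call in 1131 of 1135 cases, with 4 weaker (COL1A2 and PLOD2). The 69 named for the ASO did in 1331 of 1378, with 34 weaker and 13 stronger, and the 12 named for Tra2bPE against Naive in 228 of 240, with 12 weaker (TRA2A). None reversed. What depth limited was not tested, since the totals are on an estimated scale.

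The replicate numbers are shared by the groups, but no label says that they pair samples. The correlation of same-numbered libraries lay between 0.0265 and 0.121 for stimulation, 0.0753 and 0.108 for the ASO and 0.0929 and 0.193 for Tra2bPE against Naive, and 6 of 8, 8 of 8 and 8 of 8 libraries correlated best with their own number. Over genes with a mean of at least 5 CPM the ranges were -0.0557 to 0.320, 0.142 to 0.315 and 0.0771 to 0.431, with 4, 8 and 5 of 8. The data thus hint at pairing for the ASO comparison, where every pair was above 0.1 over these genes but not over all genes. Libraries of other numbers there reached at most 0.0206 over these genes. Tra2bPE against Naive gave a like hint over all genes, where other numbers reached at most -0.0128. Over genes of at least 5 CPM other numbers reached 0.117 in that comparison, so the ranges overlapped. With the replicate number as a block, 14645, 6165 and 10511 genes changed, and with an estimated correlation 2, 0 and 7 lists. Of the genes named, the block alone ended the call of COL1A2 for stimulation (adjusted p = 0.112) and, for the ASO, those of COL6A3 and IGF2, and TCF7 passed. The planned transcript test gave 315 genes for the ASO with the block. The share test gave 3245 and 377 with 1 CPM in 4 samples, 2119 and 107 with the 5 percent filter and 4182 and 348 with filterByExpr. Permuting the poison-exon share within replicate number left differences of -24.5 and 46.0 points with exact p = 0.125, the smallest that 4 pairs can give.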
